A study of Homo sapiens with 7 samples.

How the data were processed

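Total RNA of human breast cell lines was measured on 7 Agilent microarrays with probes for mRNAs and for non-coding RNAs. Per the labels, the RNA was copied into Cy3-labelled cRNA and hybridized in 1 colour. The groups follow the labels: 1 array of MCF10A, 3 of MCF-7 and 3 of MCF-7 MS, a form of MCF-7 whose added letters the labels do not spell out. MCF10A is generally described as a non-tumorigenic mammary epithelial line and MCF-7 as a luminal, estrogen receptor positive breast cancer line. MCF10A and MCF-7 were grown in DMEM with 10% FBS, MCF-7 also with 0.01 mg/ml insulin, and MCF-7 MS in DMEM-F12 with 2% B27, 20 ng/ml EGF and 10 ng/ml basic FGF. The labels do not say whether replicates were separate cultures, so every p-value below measures the spread between these samples alone.

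The deposited scanner files, made with Agilent Feature Extraction 10.7.1.1, give each spot's intensity on a linear scale, as a background-subtracted and spatially detrended processed signal and as mean and local background signals. Per the file headers they also hold columns of another kind, the software's yes-or-no flags, of which those for well above background, saturation and outliers were used. The authors also deposited a table of 125669 probes with a raw and a normalized column per sample. The raw columns, in intensity, were within 1% of the mean processed signal for 99.0% of values, with medians from 18.8 to 26.6. The normalized columns are log2 values that the authors' table does not describe. All of them were within 0.01 of a quantile normalization of the log2 raw columns, and each had a median of 4.53, so no scale, centring or direction stayed unknown.

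Each array held 175812 spots, and 125601 probes were left after control spots. Outlier spots were left out, repeated spots of a probe were averaged, and 37 probes without a usable spot on some array were dropped. No spot was saturated. Signals were taken as log2 of the processed signal minus each array's 75th percentile, so every level and change below is relative to the bulk of the array. Between 51.0% and 56.5% of probes were well above background on an array. For arrays, the number of samples limits the precision.

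Gene names were taken from the design's identifiers through RefSeq gene tables, which matched 58406 probes by gene number and 1492 by accession. A symbol was available for 63135 probes, and 62429 had none. Probe positions are those of the array design, in human genome build hg19. The design lists 36134 probes as mRNA and 89430 as non-coding RNA. A gene was represented by its probe with the highest mean over all 7 arrays and a probe without a symbol by itself, which gave 96244 genes. Genes called long non-coding here comprise RefSeq long non-coding RNAs, unnamed non-coding probes and non-coding probes that carry the symbol of another class of gene. A gene was tested when its probe was well above background on every array of at least 1 of the groups compared.

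Tests were run in R 4.3.3 with limma 3.58.1 and the data.table package (1.17.8), by lmFit and eBayes over all 7 arrays, with Benjamini-Hochberg adjustment and a threshold of 0.05, two-sided. The fit had 4 residual degrees of freedom, from the MCF-7 and MCF-7 MS arrays, and the lone MCF10A array was assumed to vary like the others. Gene lists, 31 in all with 555 genes on the array and 5 missing, were fixed before the data were examined. Lists with 5 or more tested members were tested with camera at the preset correlation of 0.01, adjusted over the lists. No list call in either comparison held when camera estimated the correlation itself. Fry, which asks whether a list's genes move on balance one way, was run beside it. Errors are SE of the log2 fold change unless stated.

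A probe not well above background on every array of 1 group has only a bound there. Such changes are given as at least N-fold, from the bright group's mean log2 level. The dim group's mean took, per array, the higher of the probe's own signal and the lowest signal among probes well above background.

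The genes named were set by a rule fixed before the data were examined. For MCF-7 MS against MCF-7 it takes the 8 highest and 8 lowest coding or other named genes and the 5 highest and 5 lowest long non-coding genes with a symbol. These had to pass the threshold, be well above background on every array of both groups and have groups that do not overlap. It adds the 3 largest bounds in each direction and, for a list described, up to 4 members with the smallest adjusted p. For each comparison with MCF10A it takes 5 and 3 genes per direction and members of lists with a called shift. ESR1, CD44, CD24, ALDH1A1, ALDH1A3, SOX2, NANOG and POU5F1 were to be given whatever their values. CD24 is left out as a departure from the rule, because its only probe is placed on another copy of the sequence and does not name the gene uniquely.

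The file headers place the MCF10A and MCF-7 arrays on slide 1 and the MCF-7 MS arrays on slide 2, each scanned as its own batch. The MCF-7 and MCF-7 MS replicates share numbers, but their deviations from the group mean correlated across 55134 probes at only -0.02, -0.11 and -0.06 for equal numbers, so the arrays were not treated as paired. The pipeline was tested on simulated data with the spread of these arrays. Only 100 genes were changed at each size, far fewer than the calls in these data, and every gene was drawn independently. The adjusted threshold was therefore stricter there, so the shares recovered belong to that setting alone. At a change of 1 on the log2 scale the pipeline recovered 22% of changed genes for MCF-7 MS against MCF-7, and 72% at a change of 2, with 9 false among 103 calls. For MCF-7 against MCF10A it recovered 0% and 32%, with 1 false among 33 calls, and for MCF-7 MS against MCF10A 0% and 37%, with 1 false among 38. With 1 list raised, the hypoxia list, camera recovered it in both comparisons with list tests, but for MCF-7 against MCF10A 1 of the 2 lists it called was false. In these data that list's members had an estimated correlation of 0.55 and 0.66 in those comparisons. The simulation therefore does not cover lists with correlated members.

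Alternatives covered normexp background correction (offset 50), quantile and median scaling, the authors' table, the filter on dim probes, the handling of a gene's probes, a 2-fold minimum, array weights, the moderation, a replicate block, the slide and each array left out in turn.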

Results

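The data set comprised 7 arrays, with 1 labelled MCF10A, 3 labelled MCF-7 and 3 labelled MCF-7 MS. According to its description, the series concerns how long intergenic non-coding RNAs vary in breast cancer stem cells. The share of probes well above background was 52.2% on the MCF10A array, 53.5%, 51.0% and 54.5% on the MCF-7 arrays, and 56.5%, 51.1% and 56.2% on the MCF-7 MS arrays. Replicates correlated across probes at 0.992 to 0.994 for MCF-7. Within MCF-7 MS, replicates 1 and 3 correlated at 0.991, whereas replicate 2 reached 0.972 and 0.964 with them. The median SD between replicates was 0.14 on the log2 scale for MCF-7 and 0.23 for MCF-7 MS.

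Several lineage markers did not follow the names on the labels, and the markers given here were chosen after their values were seen. The simple epithelial keratins were present on all arrays without setting the lines apart. In log2 units relative to the 75th percentile, KRT8 stood at 7.65 on the MCF-7 arrays and 8.15 on the MCF10A array, KRT18 at 5.92 and 5.19, and KRT19 at -2.14 and -2.44. EPCAM, an epithelial adhesion gene, was well above background on all 3 of them and not on the MCF10A array. The only CDH1 probe, for the epithelial cadherin, was not well above background on any array, nor was that for the basal keratin KRT5. GATA3, a luminal transcription factor, was well above background on the MCF10A array but not on the MCF-7 and MCF-7 MS arrays. Its level on the MCF10A array was only -2.90, near the lowest signal well above background there, -3.21. FOXA1, another luminal transcription factor, stood at -0.21 on the MCF10A array and -2.16 on the MCF-7 arrays. Of the 3 ESR1 probes, 2 were not well above background on any array. VIM, the mesenchymal intermediate filament, stood at 8.06 on the MCF-7 arrays and 8.03 on the MCF10A array. CDKN2A, which encodes the cell cycle inhibitor p16, stood at 8.58 and 6.88 on its 2 probes on the MCF-7 arrays. On the MCF10A array they stood at 8.20 and 6.34. On the MCF-7 arrays, 17 of 18 mesenchymal genes were detected, against 10 of 16 epithelial junction genes, 11 of 16 luminal genes and 13 of 20 basal genes. The MCF10A array was much alike, with 17, 10, 13 and 13 of these genes detected. Groups are therefore called by their labels throughout.

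**Figure D1:**
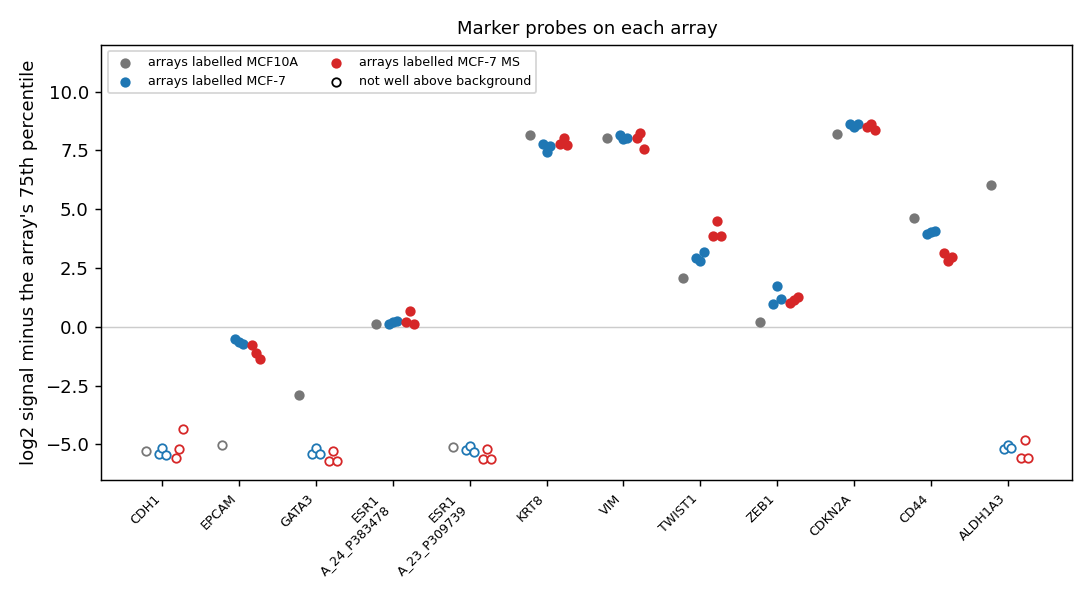
Signal of 12 marker probes on each array, as log2 signal minus the array's 75th percentile. Each point is an array, coloured by its label, and open points were not well above background. CDH1 stayed open on all 7 arrays, while VIM averaged 8.06 and CDKN2A 8.58 on the MCF-7 arrays.

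The comparison of the MCF-7 MS with the MCF-7 arrays asks what sets the MS form apart from the cells grown with serum. The imprinted long non-coding RNA H19 was higher on the MCF-7 MS arrays by 6.59 ± 0.57 on the log2 scale (n = 3 arrays per group, adjusted p = 0.00129), and all 4 of its probes were higher. Among protein-coding genes, the serpin protease inhibitors SERPINB3 and SERPINB4 were higher by 6.43 ± 0.39 and 5.94 ± 0.35 (adjusted p = 5.78e-04 for each). Of 25 hypoxia response genes, 18 were higher, among them CA9, a hypoxia-induced carbonic anhydrase, by 4.76 ± 0.30 (adjusted p = 5.85e-04). Of 15 NRF2 response genes, 6 were lower, among them the cystine transporter SLC7A11, and neither list held with an estimated correlation (adjusted p = 0.865 for each). As classes, coding genes lay lower and long non-coding genes higher.

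In all, 17247 of 51315 genes tested differed, 10093 higher and 7154 lower on the MCF-7 MS arrays, of which 2887 and 3251 changed at least 2-fold. At an unadjusted p under 0.05 the count was 24329. Levels of the groups did not overlap for 28284 genes, or 55.1%, where chance gives 10%. Long non-coding genes made up 10319 of these calls, from 32955 tested, with 7497 higher and 2822 lower. The median change of all genes was 0.13, and 0.06 to 0.14 across the scalings tried. With replicate number as a block the counts were 9844 and 5556, and leaving out a single array gave as few as 6015 and 3452, without MCF-7 replicate 2. The MCF-7 MS arrays all lay on slide 2 and the MCF-7 arrays on slide 1, so slide and group cannot be told apart.

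Other coding genes on the higher side included IGFBP3, which encodes an insulin-like growth factor binding protein (4.96 ± 0.47, adjusted p = 0.00174). The neuronal enolase ENO2 and the stress-responsive NDRG1 were higher by 4.56 ± 0.65 and 4.38 ± 0.50 (adjusted p = 0.00538 and 0.00307). PPDPFL and complement factor B, CFB, were higher by 4.30 ± 0.20 and 4.25 ± 0.22 (adjusted p = 5.78e-04 for each). The probes of IGFBP3, CA9 and NDRG1 lie at chromosome 7: 45952608 to 45952667, chromosome 9: 35677817 to 35679204 and chromosome 8: 134249719 to 134249778. The SERPINB3 probe, at chromosome 18: 61322767 to 61322826, targets a gene nearly identical to SERPINB4, so signal may be shared. Bounds were largest for the neutrophil chemokine CXCL8, on a probe the design lists as non-coding, at least 31.3-fold higher (adjusted p = 0.00299). The calprotectin subunits S100A8 and S100A9 followed at 24.2 and 8.13-fold or more (adjusted p = 0.00897 and 0.0130).

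On the lower side, the adhesion protein gene AMIGO2 differed by -4.90 ± 0.63 (adjusted p = 0.00421) and the transcription factor gene CREB3L3 by -4.08 ± 0.38 (adjusted p = 0.00162). SLC7A11, probed at chromosome 4: 139085433 to 139085492, differed by -3.85 ± 0.47 (adjusted p = 0.00365), and VIPR1, a neuropeptide receptor gene, by -3.84 ± 0.29 (adjusted p = 7.98e-04). ID2, an inhibitor of differentiation, and the ganglioside synthase B4GALNT1 differed by -3.72 ± 0.60 and -3.14 ± 0.57 (adjusted p = 0.00732 and 0.00999). POP1 differed by -3.28 ± 0.80 (adjusted p = 0.0221), but lost its call without MCF-7 replicate 1, 2 or 3, with adjusted p up to 0.0754. IFIT2 differed by -3.13 ± 0.69 (adjusted p = 0.0172) and lost its call without MCF-7 replicate 1, MCF-7 replicate 2 or MCF-7 MS replicate 1, with adjusted p up to 0.0698. The bounds were at least 11.6-fold lower for AHRR, the repressor of the aryl hydrocarbon receptor, 7.35 for the connexin gene GJB5 and 6.39 for PRR22 (adjusted p = 5.78e-04, 0.00222 and 5.78e-04).

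Among named long non-coding genes, OLMALINC was higher by 2.69 ± 0.36 (adjusted p = 0.00455), COSMOC by 2.13 ± 0.15 (adjusted p = 6.78e-04) and LINC01843 by 2.12 ± 0.24 (adjusted p = 0.00303). ZNF236-DT was higher by 2.21 ± 0.26 (adjusted p = 0.00340) on its brightest probe alone, and by 0.51, no longer past the threshold, with the mean over its probes. LINC00842 was lower, at -3.66 ± 0.26 (adjusted p = 6.85e-04), on a probe at chromosome 10: 47151119 to 47151178. LY6S-AS1 differed by -2.84 ± 0.48 (adjusted p = 0.00821), MIR181A1HG, the host of a microRNA, by -2.38 ± 0.18 (adjusted p = 7.84e-04) and ST20 by -2.28 ± 0.24 (adjusted p = 0.00232). SERTAD4-AS1 differed by -2.50 ± 0.47 (adjusted p = 0.0112), and its adjusted p was 0.0522 without MCF-7 replicate 2. The H19 probe lies at chromosome 11: 2017107 to 2017166. Of the 32 long non-coding RNAs studied in breast cancer, 6 rose and 2 fell, with the same counts adjusted over the list alone, and the list as a whole did not pass (adjusted p = 0.516). They included H19 and, on the lower side, DANCR at -1.17 ± 0.19 (adjusted p = 0.00743). EGOT rose by 0.84 ± 0.15 (adjusted p = 0.0102) on all 4 probes.

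Coding genes moved apart from most other classes of probe. Of 14042 coding genes, 1688 were higher and 3998 lower, with a median of -0.26. Of 2715 named long non-coding genes, 728 were higher and 189 lower, with a median of 0.30, and of 23112 unnamed non-coding probes 5391 were higher and 1857 lower, with a median of 0.22. The signs of these 3 medians held under all 6 scalings, but their size fell with normexp background correction and the 75th percentile, to -0.17, 0.17 and 0.11. Small RNAs, 292 in number, had 16 higher and 32 lower, with a median of 0.00. Of 3542 unnamed probes listed as mRNA, 786 were higher and 256 lower, with a median of 0.25. The rise was therefore not confined to non-coding probes. Array by array, the long non-coding median minus the coding median was 0.39, 0.69 and 0.33 for MCF-7 MS replicates 1, 2 and 3, against -0.07 to 0.06 on the MCF-7 arrays.

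**Figure D2:**
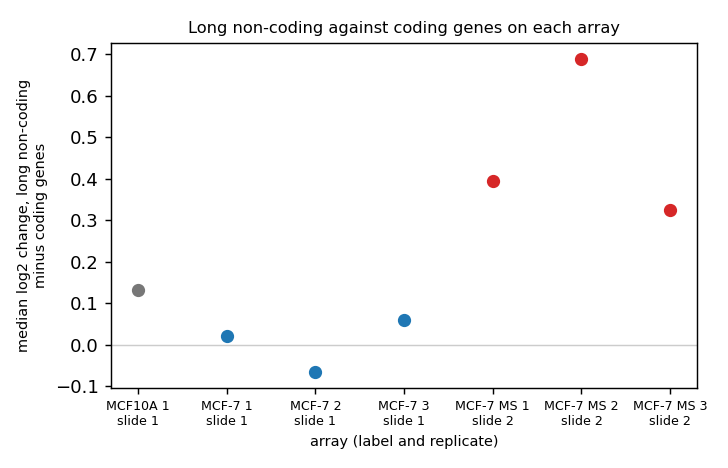
Median log2 change of long non-coding genes minus that of coding genes, for each array against the mean of the MCF-7 arrays, or of the other MCF-7 arrays for an MCF-7 array. The MCF-7 MS arrays lie at 0.33 to 0.69 and the MCF-7 arrays at -0.07 to 0.06, with MCF10A at 0.13.

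Of 31 gene lists, 4 shifted by camera, 2 up and 2 down, while quantile normalization and the authors' table each gave 2 up and 9 down, and normexp with quantile normalization 2 up and 10 down. Camera set each list against all 51315 genes tested, 32955 of them long non-coding. Coding genes had a median of -0.26 against 0.13 for all genes, so the down calls carry part of that class difference. Only the hypoxia list was also set against coding genes alone. All 4 kept an adjusted p under 0.05 in each scaling, with the replicate block and without any single array, but not with an estimated correlation, where the smallest adjusted p was 0.865. Of 25 hypoxia response genes, 18 rose and 7 did not pass, or 19 rose adjusted over the list alone, with a median of 1.55 (camera adjusted p = 4.38e-06, and 0.865 as the adjusted p with an estimated correlation). They included the transcriptional repressor BHLHE40 at 1.78 ± 0.16 (adjusted p = 0.00137) and the aldolase ALDOC at 3.06 ± 0.37 (adjusted p = 0.00359), beside CA9 and NDRG1. Of 15 NF-kB and inflammatory genes, 8 rose, or 10 adjusted over the list alone, with a median of 1.06 that was 0.61 without MCF-7 MS replicate 2 (camera adjusted p = 0.0160, and 0.865 as the adjusted p with an estimated correlation). The mitochondrial superoxide dismutase SOD2 rose by 2.36 ± 0.35 (adjusted p = 0.00579), and the mRNA probe of CXCL8 was at least 4.20-fold higher (adjusted p = 0.00730).

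Of 15 NRF2 response genes, which serve the defence against oxidants, 6 fell and 9 did not pass, or 7 fell adjusted over the list alone, with a median of -0.44 (camera adjusted p = 0.00198, and 0.865 as the adjusted p with an estimated correlation). SLC7A11 was joined by the thioredoxin reductase TXNRD1 at -1.59 ± 0.20 (adjusted p = 0.00416), G6PD, of the pentose phosphate pathway, at -1.52 ± 0.25 (adjusted p = 0.00777) and the sulfiredoxin SRXN1 at -1.54 ± 0.28 (adjusted p = 0.0104). Of 26 genes of the G1 to S transition and DNA replication, 4 fell, 1 rose and 21 did not pass, or 3 fell adjusted over the list alone, with a median of -0.54 that was -0.30 without MCF-7 MS replicate 2 (camera adjusted p = 1.41e-04, and 0.865 as the adjusted p with an estimated correlation). That count of 4 in 26 was a smaller share than the 28.5% of all coding genes that fell. Cyclin E1, CCNE1, fell by 0.82 ± 0.13 (adjusted p = 0.00775) and the checkpoint protein gene CLSPN by 1.51 ± 0.26 (adjusted p = 0.00854). Fry passed the hypoxia and NRF2 lists (adjusted p = 0.0256 and 0.0169) and gave adjusted p = 0.110 for the G1 to S list and 0.0649 for the NF-kB list.

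**Figure D3:**
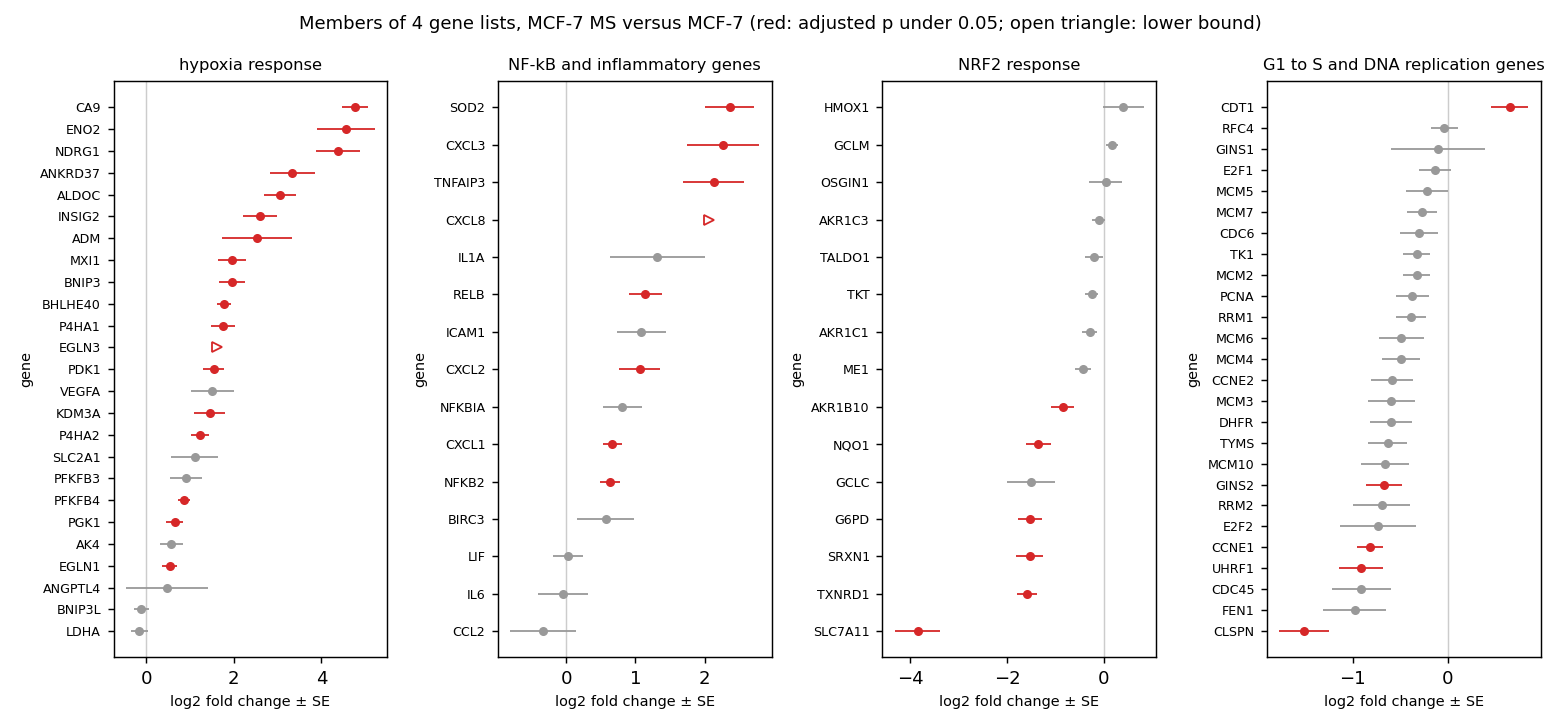
Log2 fold change, MCF-7 MS against MCF-7, of each tested member of the 4 shifted lists, with SE bars and n = 3 arrays per group. Red marks members past the adjusted threshold, 18 of 25 in the hypoxia list, and open triangles mark lower bounds for probes not well above background on the MCF-7 arrays.

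Of 12 stem cell markers, 2 were higher and 5 lower, the same counts as adjusted over the list alone. The list lay near the threshold, lower without passing it (camera adjusted p = 0.0647, fry adjusted p = 0.0545), but passed without MCF-7 MS replicate 1 (adjusted p = 0.0386) and with quantile normalization (adjusted p = 0.0405). THY1, a surface glycoprotein, differed by -1.38 ± 0.15 (adjusted p = 0.00284) and the integrin ITGA6 by -1.11 ± 0.17 (adjusted p = 0.00593). CD44, the hyaluronan receptor used as a breast cancer stem cell marker, differed by -1.04 ± 0.14 (adjusted p = 0.00480), while its dimmer probe stood at 1.62 on MCF-7 and 1.72 on MCF-7 MS arrays. ALDH1A1 did not pass (0.39 ± 0.17, adjusted p = 0.108), nor did POU5F1 (0.13 ± 0.25, adjusted p = 0.709) or ESR1 (0.14 ± 0.18, adjusted p = 0.553). The other of the 2 ALDH1A1 probes was not well above background on any array, so detection of that gene rests on 1 probe. ALDH1A3 was not well above background in either group, and the only SOX2 and NANOG probes were not well above background on any array.

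The comparison of the MCF-7 with the MCF10A array sets the labelled cancer line against the labelled non-tumorigenic line. Of 22 genes of the ATF4 and amino acid response, 7 were higher on the arrays labelled MCF-7, such as the serine synthesis enzyme PSPH (3.62 ± 0.21, n = 3 against 1, adjusted p = 1.32e-04). Of 24 interferon-stimulated genes, 11 were lower, such as the antiviral GTPase MX1 (-4.00 ± 0.21, adjusted p = 8.89e-05), and neither list held with an estimated correlation (adjusted p = 0.550 for each). ALDH1A3, a retinal dehydrogenase gene counted among stem cell markers, was at least 711-fold lower on the MCF-7 arrays (adjusted p = 1.79e-05). The fatty acid carrier FABP5 and the estrogen-metabolizing CYP1B1 were higher by 6.32 ± 0.21 and 6.25 ± 0.33 (adjusted p = 1.79e-05 and 8.94e-05).

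In all, 8332 of 53057 genes differed, 4385 higher and 3947 lower on the MCF-7 arrays, and 16460 had an unadjusted p under 0.05. That balance turned to 4595 higher and 4957 lower under normexp with the 75th percentile, and to 4851 and 6015 under normexp with quantile normalization. Long non-coding genes made up 4375 of 34002 tested, 2260 higher and 2115 lower, which turned to 2070 and 2639, and to 2287 and 3362, under the same settings. Both groups lay on slide 1. A fit of those 4 arrays alone gave 15533 genes and 8441 long non-coding genes. Without MCF-7 replicates 1, 2 and 3 in turn the counts were 5342, 4916 and 4982, and without MCF-7 MS replicate 2, which enters only through the pooled spread, 15759.

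The membrane protein gene MCTP2 was higher by 6.82 ± 0.27 (adjusted p = 3.69e-05), the mitochondrial CHCHD10 by 6.32 ± 0.19 (adjusted p = 1.79e-05) and the secreted protease inhibitor SLPI by 5.95 ± 0.40 (adjusted p = 2.35e-04). On the lower side stood the small RNAs SNAR-F (-6.41 ± 0.53, adjusted p = 5.06e-04) and SNAR-G1 (-5.52 ± 0.19, adjusted p = 2.19e-05), from a family of near-identical copies that share signal. SNORD123, GPRC5B, an orphan receptor gene, and NPY, which encodes neuropeptide Y, differed by -6.28 ± 0.27, -5.65 ± 0.35 and -5.48 ± 0.32 (adjusted p = 4.77e-05, 1.68e-04 and 1.25e-04).

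Among named long non-coding genes, LINC03033 was higher by 5.66 ± 0.54 (adjusted p = 9.42e-04), HCP5 by 4.55 ± 0.34 (adjusted p = 3.42e-04) and FAM230B by 4.31 ± 0.44 (adjusted p = 0.00125). C16orf95-DT was lower, at -4.98 ± 0.36 (adjusted p = 3.24e-04), as were LINC01842 at -4.24 ± 0.32 (adjusted p = 3.55e-04) and SMC5-DT at -3.07 ± 0.52 (adjusted p = 0.00934). With the mean over a gene's probes FAM230B was at 0.17 and SMC5-DT at -0.31, neither past the threshold, and LINC01842 turned to 0.69. CD44 did not pass (-0.61 ± 0.20, adjusted p = 0.0890), nor did ALDH1A1 (0.25 ± 0.24, adjusted p = 0.515), ESR1 (0.04 ± 0.26, adjusted p = 0.926) or POU5F1 (-0.22 ± 0.35, adjusted p = 0.714). The melanophilin gene MLPH, used as a luminal marker and named after its values were seen, was at least 34.0-fold lower (adjusted p = 7.47e-05).

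Of 31 lists, 12 shifted by camera, 10 up and 2 down, 11 of them also in the fit within slide 1, and with an estimated correlation none did, the smallest adjusted p being 0.550. Fry passed 4 of the 12, the interferon-stimulated, NRF2, reference gene and pluripotency lists (adjusted p = 0.00494, 0.00622, 0.00482 and 0.00146). It gave adjusted p = 0.0531 for ATF4, 0.0898 for glycolysis and for NF-kB, 0.109 for ribosomal proteins, 0.153 for cholesterol, glucocorticoid and basal genes, and 0.163 for fatty acid synthesis. Fry alone passed 5 other lists, with the luminal identity (0.0123), Notch (0.0103), neural progenitor (0.0120) and Wnt (0.00915) lists lower and the estrogen response list (0.00915) higher on the MCF-7 arrays, as adjusted p. Of 22 genes of the ATF4 and amino acid response, 7 rose and 15 did not pass, or 9 rose adjusted over the list alone (median 1.08, camera adjusted p = 5.27e-05, and 0.550 as the adjusted p with an estimated correlation). Beside PSPH, the stress gene DDIT4 rose by 3.84 ± 0.27 (adjusted p = 2.80e-04), ALDH1L2 by 2.63 ± 0.28 (adjusted p = 0.00149) and PSAT1 by 2.03 ± 0.28 (adjusted p = 0.00420). Of 24 interferon-stimulated genes, 11 fell and 13 did not pass, or 14 fell adjusted over the list alone (median -1.64, camera adjusted p = 5.17e-04, and 0.550 as the adjusted p with an estimated correlation). IRF9 differed by -2.78 ± 0.19 (adjusted p = 2.52e-04), and IFI27 and RSAD2 were at least 13.6-fold and 4.05-fold lower (adjusted p = 1.98e-04 and 2.82e-04). Of 16 NF-kB and inflammatory genes, 4 fell, the same count as adjusted over the list alone (median -0.86, or -0.73 with a member at its bound, camera adjusted p = 0.0237, and 0.550 as the adjusted p with an estimated correlation). NFKB2 and RELB differed by -1.42 ± 0.21 and -2.27 ± 0.34 (adjusted p = 0.00536 and 0.00582).

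The cholesterol, NRF2, glycolysis and fatty acid synthesis lists were among the 10 that camera called higher, and fry passed only NRF2 of these. Camera set them against all genes tested, whose median was -0.12, while coding genes had a median of -0.01. Lists of coding genes therefore lean up in this comparison. The shares of glycolysis and ribosomal protein genes called higher lay near that of all coding genes. Their list medians were 0.53 and 0.28. Of 24 cholesterol genes, 5 rose and 1 fell, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.00523, and 0.550 as the adjusted p with an estimated correlation), with STARD4, a sterol carrier, at 2.62 ± 0.40 and the mevalonate pathway enzyme MVD at -1.68 ± 0.25. Of 15 NRF2 response genes, 5 rose, or 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00983, and 0.550 as the adjusted p with an estimated correlation), with the aldo-keto reductase AKR1C3 at least 16.1-fold higher and AKR1C1 at least 2.71-fold. Of 15 glycolysis enzymes, 2 rose and 1 fell, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.0166, and 0.550 as the adjusted p with an estimated correlation), with the lactate dehydrogenase subunit LDHB at 2.17 ± 0.18. Of 15 fatty acid synthesis genes, 4 rose and 1 fell, the same as adjusted over the list alone (camera adjusted p = 0.0299, and 0.552 as the adjusted p with an estimated correlation), with the malic enzyme ME1 at 1.45 ± 0.24 and ACACA at 1.93 ± 0.34.

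Of 31 cytosolic ribosomal protein genes, 5 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0138, and 0.657 as the adjusted p with an estimated correlation), with RPS6 at 2.93 ± 0.18. Of 15 reference genes, often taken as stable, 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0271, and 0.550 as the adjusted p with an estimated correlation), with the cyclophilin PPIA at 1.56 ± 0.18. Of 16 glucocorticoid and progestin response genes, 3 rose and 1 fell, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.0271, and 0.550 as the adjusted p with an estimated correlation), with TSC22D3 at 2.12 ± 0.29. Of 6 pluripotency factors, 3 rose, also adjusted over the list alone (camera adjusted p = 0.0443, and 0.550 as the adjusted p with an estimated correlation), with SALL4 at least 29.5-fold higher. That list gave an adjusted p of 0.123 within slide 1, and of 0.0502, 0.0982 and 0.0620 without MCF-7 MS replicates 1, 2 and 3. Of 13 basal and myoepithelial markers, 3 rose, also adjusted over the list alone (camera adjusted p = 0.0474, and 0.550 as the adjusted p with an estimated correlation), a call that held in 4 of 6 scalings and was lost without MCF-7 replicate 2 (adjusted p = 0.0860) or MCF-7 MS replicate 1 (adjusted p = 0.0502). They were ANXA1 at 1.19 ± 0.23, whose adjusted p was 0.0508 without MCF-7 replicate 3, the growth factor receptor EGFR at 1.38 ± 0.28, and the keratin KRT14, at least 15.4-fold higher on a probe that its other probes did not all follow. KRT14 lost its call without MCF-7 replicate 2 or 3 (adjusted p = 0.0672 and 0.0604).

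The comparison of the MCF-7 MS with the MCF10A array had MCTP2, SLPI, IGFBP3, NDRG1 and SERPINB4 among its higher genes, by 8.24 ± 0.27, 7.30 ± 0.40, 6.74 ± 0.67, 6.51 ± 0.71 and 6.51 ± 0.50 (n = 3 against 1, adjusted p from 1.75e-05 to 0.00120). The lower side was held by copies of the small snaR RNAs, SNAR-F at -8.07 ± 0.52, SNAR-G2 at -7.95 ± 0.54, SNAR-D at -7.79 ± 0.59, SNAR-H at -7.69 ± 0.57 and SNAR-B2 at -7.68 ± 0.62. H19 was higher by 5.47 ± 0.81 (adjusted p = 0.00413) and HCP5, a transcript of the HLA region, by 4.68 ± 0.33 (adjusted p = 2.34e-04). ALDH1A3 was at least 693-fold lower on the MCF-7 MS arrays. CD44 differed by -1.65 ± 0.20 on its brighter probe. Its dimmer probe stood at 1.84 on the MCF10A array and 1.72 on the MCF-7 MS arrays.

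C16orf95-DT and LINC00842 were lower, at -4.85 ± 0.36 and -3.88 ± 0.37 (adjusted p = 2.65e-04 and 6.81e-04). FAM230B was higher by 4.42 ± 0.44 (adjusted p = 7.98e-04) and LINC01842 lower, at -3.19 ± 0.32 (adjusted p = 7.83e-04), but both lost their call with the mean over a gene's probes, at 0.38 and -0.24. ALDH1A1 (0.63 ± 0.24, adjusted p = 0.105), ESR1 (0.19 ± 0.26, adjusted p = 0.655) and POU5F1 (-0.09 ± 0.35, adjusted p = 0.884) did not pass. In all, 11167 of 53565 genes differed, 5593 higher and 5574 lower, or 5987 and 6826 under normexp with quantile normalization, and 18536 had an unadjusted p under 0.05. Long non-coding genes made up 6240 of 34396 tested, 3691 higher and 2549 lower. Without MCF-7 MS replicate 2 the counts were 16798 and 9487. The groups lay on different slides, so slide and group cannot be told apart, and no list test was planned here.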

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

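The fit within slide 1, and for gene lists the median, normexp with quantile and authors' table scalings, were chosen after seeing the data, all other settings before. For genes and long non-coding genes changed between MCF-7 MS and MCF-7, a 2-fold minimum gave 6138 and 3367, no filter on dim probes 9338 and 5543, array weights 32123 and 19955, and the replicate block 9844 and 5556. Leaving out each array in turn gave 6015 to 18825 and 3452 to 11016. For MCF-7 against MCF10A, array weights gave 23317 and 13561, the fit within slide 1 gave 15533 and 8441, and leaving out each array 4916 to 15759 and 2508 to 8591. The filter on all arrays gave 2773 long non-coding genes there, from fewer genes tested. For MCF-7 MS against MCF10A, array weights gave 29723 and 17968, and leaving out each array 8453 to 16798 and 4683 to 9487. Lists shifted between MCF-7 MS and MCF-7 numbered 11 with quantile normalization, 9 of them down, 12 with normexp and quantile normalization, 10 of them down, 11 with the authors' table, 9 of them down, and 4 to 8 without each array. Camera with an estimated correlation called 0 lists in both comparisons, where fry called 6 and 9, only 2 and 4 of them among the camera calls. Without each array, 10 to 12 lists shifted between MCF-7 and MCF10A. With the mean over a gene's probes HOTAIR reversed to -0.41 and LAMC2 to -0.97 in MCF-7 MS against MCF-7, and LINC01842 to 0.69 in MCF-7 against MCF10A, because their probes go opposite ways. Apart from the filter and the probe mean, the cause was not tested. Fewer arrays alone cannot be the cause throughout. For MCF-7 against MCF10A the count of 8332 rose to 15759 without MCF-7 MS replicate 2 and to 15533 within slide 1. Over all settings, single named genes and list members kept direction and side of the threshold in 2639 values for MCF-7 MS against MCF-7, with 162 weaker, 55 stronger and 2 reversed, and in 1208, 75, 15 and 1 for MCF-7 against MCF10A. Slide as a block was not run for either comparison with MCF-7 MS, since slide 2 holds that group alone, and for the same reason it tests nothing in MCF-7 against MCF10A. Signal over background limits the rest, since only 51.0% to 56.5% of probes on an array were well above it.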

Other observations

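Further gene groups differed in part between the MCF-7 MS and MCF-7 arrays without a shift of the whole list by camera in the main setting. Over the 6 scalings, camera called the p53 list in 4, the reference genes in 3 and the interferon-stimulated genes in 2. It called the cholesterol, estrogen response, mesenchymal and Notch lists in none. Fry did pass the p53, estrogen response, reference gene and pluripotency lists (adjusted p = 0.0157, 0.0169, 0.0169 and 0.0169), and some lists passed camera without single arrays. Of 25 cholesterol synthesis and uptake genes, 9 rose and 2 fell, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.103, but 0.0348 without MCF-7 replicate 1 and 0.0387 without MCF-7 MS replicate 2). PCSK9, which lowers the LDL receptor, was at least 7.13-fold higher (adjusted p = 5.78e-04), and the sterol-regulated INSIG1 rose by 3.05 ± 0.35 (adjusted p = 0.00307). Of 24 estrogen response genes, 9 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.516), with cyclin D1, CCND1, at -2.76 ± 0.25 (adjusted p = 0.00147). Of 18 interferon-stimulated genes, 7 fell, also adjusted over the list alone (camera adjusted p = 0.0647, but 0.0417 without MCF-7 replicate 3 and 0.0344 without MCF-7 MS replicate 3), with IFIT3 at least 5.86-fold lower (adjusted p = 0.00571) and STAT1 at -1.03 ± 0.21 (adjusted p = 0.0131, and 0.0567 without MCF-7 replicate 2).

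Of 20 p53 targets, 5 fell, or 4 adjusted over the list alone. Camera gave adjusted p = 0.0551, but 0.0348 without MCF-7 replicate 1 and 0.0386 without MCF-7 MS replicate 1. The list's median of -0.27 was close to the -0.26 of all coding genes, so its shift was not set apart from theirs. Those lower included TP53I3 at -1.92 ± 0.18 (adjusted p = 0.00162) and AEN at -1.18 ± 0.16 (adjusted p = 0.00448). Mesenchymal genes went both ways, with 3 of 17 higher and 5 lower, or 4 and 5 adjusted over the list alone (camera adjusted p = 0.618). The cadherin CDH2 differed by -1.78 ± 0.25 (adjusted p = 0.00512) and the collagen crosslinker LOX, also a hypoxia-induced gene, by 3.74 ± 0.56 (adjusted p = 0.00587). Of 9 Notch targets and receptors, 2 rose, also adjusted over the list alone (camera adjusted p = 0.646), among them HEY1 at 2.70 ± 0.30 (adjusted p = 0.00290). Of the reference genes, 2 of 15 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.238), with ACTB at -1.26 ± 0.15 (adjusted p = 0.00331).

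The tests below were chosen after the results were seen, apart from those on probe brightness and on MCF-7 MS replicate 2 for the hypoxia list and the other splits of the arrays. Among the 10 splits of the 6 MCF-7 and MCF-7 MS arrays into 3 and 3, only 1, the real one, called as many as 17247 genes, and limma called at most 0 in the others, with 227 to 714 at an unadjusted p under 0.05 against 24329. For long non-coding genes it was again 1 split, with 10319 against at most 0. For lists, 8 of 10 splits shifted as many as the real 4, the highest other being 9. Camera called the hypoxia list in 6 of the 9 other splits, with an adjusted p as small as 1.25e-07 against 4.38e-06 in the real one. Fry gave that list an adjusted p of 0.71 or more in the other splits, against 0.0256. With 10 splits a share under 0.05 is out of reach, and every other split keeps part of the real difference, as its sides hold unequal numbers of MCF-7 MS arrays, so nothing is said of chance.

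Coding genes lay below long non-coding genes on the MCF-7 MS arrays, by 0.48 between the class medians. Within cells of equal probe GC content and brightness the difference was 0.53, with an SD of 0.19 over the MCF-7 MS arrays. Long non-coding genes lay above coding genes in 44 of 50 cells, which argues against GC content. The matching cannot decide on brightness, which was averaged over arrays that carry the difference. Added signal such as genomic DNA would lift dim probes most. The brightest of 3 equal groups of long non-coding genes had a median change of 0.36 and the dimmest 0.12. Brightness was averaged over all 7 arrays, so genes higher on the MCF-7 MS arrays also rank as brighter, and these values cannot decide on added signal. Without MCF-7 MS replicate 2 the difference was 0.35, so that array is not the sole source. A slide effect cannot be told apart from the group, since the MCF10A array of slide 1 stood at 0.13, below every MCF-7 MS array, and a difference in the cells or their medium is an untested, equally open candidate.

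Hypoxia genes were higher on the MCF-7 MS arrays, and this may reflect culture, as an untested hypothesis. The labels give the groups different media. The 15 glycolysis enzymes did not shift with the hypoxia list, with 3 higher, 2 lower and a median of -0.16 (camera adjusted p = 0.819). The hypoxia list's median of 1.55 lay above all of 10000 random coding lists matched on brightness, at percentile 100. The highest random median was 0.48. This argues against brightness, though brightness was again averaged over all the arrays, MCF-7 MS among them. Without MCF-7 MS replicate 2 the list's median was still 1.37, with a camera adjusted p of 4.11e-07, so that array alone is not the source. The small camera p adds little, since it did not hold with an estimated correlation (adjusted p = 0.865). Camera also called the list in 6 of the 9 splits that mixed the groups. Those splits keep part of the real difference, so they cannot decide on that call. A slide effect cannot be told apart, as each slide holds its own groups, and the spike-in probes, with a median difference of 0.0828 and a range of -0.18 to 0.63 on the log2 scale, cannot decide it.

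Several lineage markers ran against the labels on the arrays labelled MCF-7 and MCF10A. Failed probes may explain single genes, but of 13 epithelial or luminal genes with several probes each, 3, GRHL2, MLPH and PRLR, had every probe not well above background on every MCF-7 array, 3 had some and 7 had no such probe, and the MLPH probes were well above background on the MCF10A array. The bound of 3 was written after marker probes had been seen, and the value lies on it, so this argues only weakly against failed probes. CDKN2A, a locus described as deleted in MCF-7 and MCF10A, was at or above percentile 98.3 on all 7 arrays, which fits RNA from cells other than the labelled lines as a candidate explanation found on these same data. No biological explanation was tested, and the data name no other source.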
